A study of Homo sapiens with 12 samples.

How the data were processed

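Messenger and other RNA was measured by RNA sequencing in 12 libraries from C-28I2, an immortalised human chondrocyte line. The 4 groups had 3 libraries each: control cells, cells given interleukin-1β (IL-1β) alone, and cells given IL-1β followed by extracellular vesicles of unstimulated or of TGF-β-stimulated neutrophils. Per the labels' protocols, IL-1β was used at 20 ng/ml for 24 h and the cells were washed 3 times before vesicles were added. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

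Per the labels' protocols, libraries were made with the NEBNext Ultra II Directional kit and read as 150 bp pairs, at 4 to 6 gigabases per sample. Per the submitters' processing notes, reads were trimmed with fastp, aligned to hg38 with STAR and quantified with RSEM; versions and the gene annotation are not given in the sources used here. The authors deposited 1 table of TPM values (length-normalized transcript abundances) with 61860 rows, and each library sums to 1000000 TPM. TPM holds no read depth, so the number of reads behind a value is unknown and no counting interval was computed. Whether strand was used in the quantification is not stated. Among 3051 long noncoding genes whose exons overlap the opposite strand of a gene at 1 TPM or more, 873 (28.6%) had a higher mean TPM than that partner. The row ENSG00000269968, antisense to GAPDH, had a mean of 14080 TPM beside 6053 TPM for GAPDH. Values of antisense RNAs, and of genes whose exons overlap a gene on the other strand, may therefore hold reads of the other gene.

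TPM values were analysed as log2(TPM + 1). Rows with a mean of at least 1 TPM over the 12 libraries were tested, which left 18257 rows. One limma model (version 3.58.1, R 4.3.3) with a mean per group and empirical Bayes moderation with a mean-variance trend gave each contrast, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. The moderated F test of the same fit tested any difference among the groups. The median 95% half-width of a fold change between groups of 3 was 0.42 on the log2 scale. For gene groups, 32 lists were fixed before the data were examined, and the 29 with at least 5 tested genes entered limma's camera with its preset correlation of 0.01; camera with an estimated correlation and fry were run beside it. Simulated data were drawn independently for each gene from its mean over the 12 libraries and its spread within groups. In them 200 of 18257 genes were changed in the IL-1β group, by 2-fold or 4-fold on the log2(TPM + 1) scale. For IL-1β against control 54.7% of 2-fold and 88.9% of 4-fold changes were recovered, with 5.56% and 6.40% of calls false. The simulation held no structure shared between genes, so these shares may differ in the real libraries.

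The genes named in the text were set by a rule fixed before the data were examined. It takes the 10 largest positive and 10 largest negative fold changes among genes past the threshold whose groups do not overlap and that carry a symbol. Where none passed in a direction, it takes the 3 with the smallest unadjusted p, stated as not passing. SFRP5, named in the series title, was added whatever its level, and up to 4 members were taken from each described list. Genes named outside this rule were chosen after their values were seen. Single values were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1. Positions and overlaps come from GENCODE v44 on hg38, matched by symbol.

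The alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 TPM, quantile normalization, median-ratio scaling, TPM rescaled without mitochondrial and ribosomal RNA, a fit of only the groups compared, no variance trend, the replicate number as a block, an estimated correlation in camera, and leaving out each library in turn. Added after the data were seen were a correction of each library for transcript GC content, the removal of libraries 1 and 3 of the unstimulated-vesicle group, a test of protein-coding genes alone, and both vesicle groups against control. GC content was known for 97.4% of tested rows.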

Results

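Gene expression was measured as TPM in 12 libraries of C-28I2 chondrocytes, with 3 libraries in each of 4 groups. IL-1β is an inflammatory cytokine that drives cartilage breakdown. Extracellular vesicles are membrane particles shed by cells, here by neutrophils that were unstimulated or stimulated with TGF-β. The series title names secreted frizzled related protein 5 (SFRP5), a Wnt inhibitor. Read depth per library is unknown, and 24694 to 26973 rows per library had a value above 0. The limma F test called 123 genes for any difference among the 4 groups.

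The first comparison asks what IL-1β did to the cells. Chemokines and cytokines rose most. CXCL1, a neutrophil attractant, rose from 6.74 ± 4.16 TPM in control cells to 161 ± 15.3 TPM (SD, n = 3 each), a log2 fold change of 4.51 ± 0.28 (SE). IL6 rose from 1.52 ± 0.37 to 14.02 ± 0.38 TPM, and C3, the central complement component, from 4.17 ± 0.16 to 55.8 ± 15.1 TPM. CXCL8 rose from 12.6 ± 8.63 to 91.8 ± 25.2 TPM. Interferon-stimulated genes rose as a group beside the inflammatory genes. The limma test called 113 of 18257 genes, 112 higher and 1 lower with IL-1β. All 113 were separated between the groups, as were all called genes of every other comparison, so this adds little to the call. Among all genes 9.30% were separated, where chance gives 10%. At an unadjusted p under 0.05 there were 1069, or 5.855%, where chance gives 5%.

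**Figure D1:**
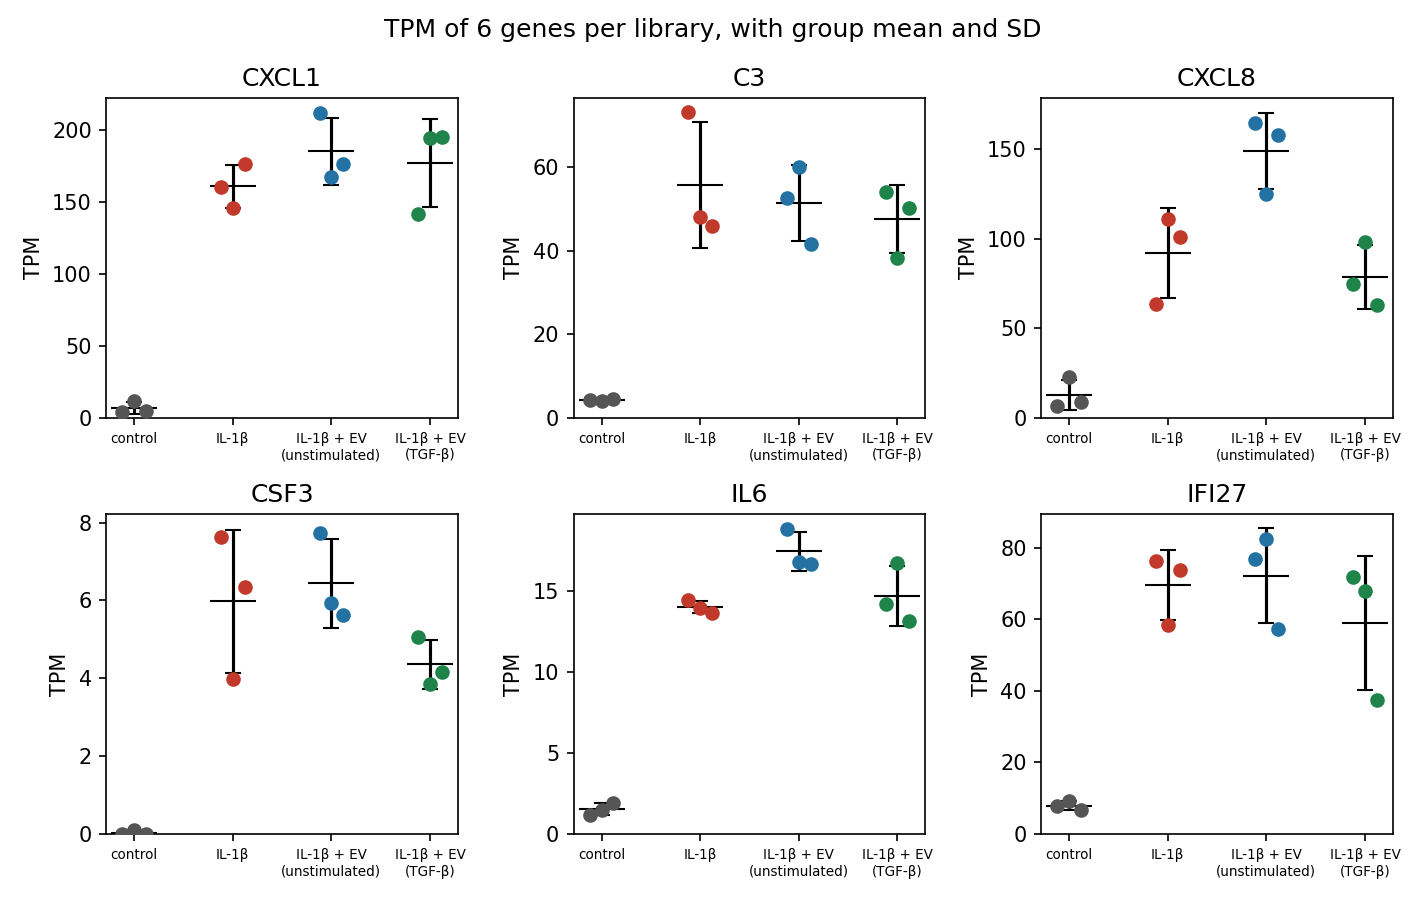
TPM of CXCL1, C3, CXCL8, CSF3, IL6 and IFI27 in each of the 12 libraries (points), with group mean and SD (bars), on linear axes from 0. CXCL1 averaged 6.74 TPM in control cells and 161, 185 and 177 TPM in the 3 groups given IL-1β.

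The 10 largest increases among called genes with a symbol were led by CXCL1 and C3. Next came IFI27 (2.99 ± 0.23), CXCL2 (2.96 ± 0.23), CXCL8 (2.91 ± 0.36) and MIR5695 (2.90 ± 0.40). The others were the colony-stimulating factors CSF3 (2.72 ± 0.21) and CSF2 (2.68 ± 0.26), MIR3142HG (2.64 ± 0.22) and IL6 (2.59 ± 0.14). Values are log2 fold change ± SE, each with limma adjusted p of 0.0041 or lower. ENSG00000251144, a called row without a symbol, rose by 2.75. CXCL1, CXCL2 and CXCL8 lie together on chromosome 4, with CXCL1 at 73869393 to 73871308. MIR5695 is an 85 bp row on chromosome 19 and was listed at 0 in all control libraries. With unstimulated vesicles against IL-1β alone its log2 fold change was -2.90, so the rise was not kept there. As a short RNA row its value is uncertain. MIR3142HG is a long noncoding RNA on chromosome 5 whose exons hold MIR146A. UPK3BL3P, a pseudogene on chromosome 7 that shares 450 bp of exon with POLR2J4 and so is uncertain, was the only gene that fell, by 1.87. Of the 113 genes, 95 were protein-coding, and 11 of the other 18 share exon sequence with another called gene on the opposite strand, among them ENSG00000228318 at MX1 and ENSG00000257452 at OAS1, so their own change is uncertain. Of the 95, 31 overlap exons of a gene on the other strand, including IL6 (428 bp with IL6-AS1), PTGS2 (219 bp with PACERR), TNFAIP3 (95 bp with WAKMAR2) and LIF (86 bp with LIF-AS1), and their values may hold reads of that gene. For 12 of the 31, among them PLAU (915 bp with C10orf55) and XAF1 (2535 bp with PRAL), a gene on the other strand was itself called.

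Of 15 cytokine and chemokine genes tested, 9 rose over all genes tested and 14 when adjusted over the list alone, with a median log2 fold change of 1.57. Besides the genes above, CXCL6 (1.60), IL32 (1.56) and LIF (1.10) rose. Of 22 NF-κB response genes, 12 rose (17 adjusted over the list alone), including NFKBIZ (2.05), ZC3H12A (1.97) and TNFAIP3 (1.81), a feedback inhibitor of NF-κB. Of 35 interferon-stimulated genes, 25 rose (31 adjusted over the list alone) and all 35 had a positive fold change. IFI27 led, followed by CXCL10 (2.47), IFI6 (2.43) and OAS2 (2.40). Camera called these 3 lists, and the calls held with an estimated correlation, at adjusted p = 3.5e-05, 2.4e-05 and 0.0033.

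Of 19 matrix proteases, 3 rose: the cysteine protease CTSS (2.46), the collagenase MMP13 (1.27) and PLAU (0.64), the urokinase-type plasminogen activator. MMP13 went from 1.17 ± 0.23 to 4.34 ± 1.32 TPM, while MMP3 was listed at 0 in every library. The list was called by camera, with adjusted p = 0.16 with an estimated correlation. ABCG1, a cholesterol exporter, was the only one of 10 cholesterol efflux genes past the threshold (1.19), with 4 adjusted over the list alone, and this list had adjusted p = 0.056 with an estimated correlation. LCN2 (1.45), which is also in the NF-κB list, was the only one of 10 tested neutrophil transcripts past the threshold over all genes, and G0S2 (0.72) also rose adjusted over the list alone; adjusted p = 0.16 with an estimated correlation. TGF-β targets (median 0.18), fibrous matrix genes (0.14) and immediate early genes (0.15) were called higher, and mitochondrial transcripts (-0.15) and ribosomal proteins (-0.02) lower, with no member past the threshold and adjusted p of 0.43 to 0.75 with an estimated correlation. Adjusted over the list alone, 3 of 22 TGF-β targets and 1 of 17 fibrous matrix genes rose. Fry, which tests whether a list moves one way without comparing it with other genes, called 7 lists for IL-1β.

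Of 27 cartilage matrix genes listed, only 11 reached the level set for testing, and none of them passed. COL2A1, the main cartilage collagen, was below that level, at 0.83 ± 0.24 TPM in control and 0.76 ± 0.15 TPM in IL-1β cells. ACAN was also below it, at 0.08 and 0.20 TPM. The response of these untested genes to IL-1β is therefore not known from these data. Of 24 Wnt ligands and receptors, WNT10B rose (1.02), and none of 8 Wnt inhibitors or 11 Wnt targets passed. PTGS2 (1.93), the inducible cyclooxygenase, and the protease inhibitor SERPINE2 (0.98) rose in lists that camera did not call, and IRAK2 (1.19) is in the NF-κB list as well as in the IL-1 receptor list, which was not called. With a fit of only the 6 libraries compared, the count fell to 54 and CXCL8 lost its call. UPK3BL3P lost its call without control replicate 1 or 3. Leaving out control replicate 2 cut the called lists from 11 to 5, and leaving out IL-1β replicate 1 cut them to 6.

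SFRP5 (chromosome 10, 97766751 to 97771999, minus strand, 3 exons in GENCODE v44) was below 1 TPM in all 12 libraries, under the level set for testing. It averaged 0.10 ± 0.11 TPM in control cells, 0.10 ± 0.18 TPM with IL-1β alone, 0.08 ± 0.07 TPM with vesicles of unstimulated neutrophils and 0.45 ± 0.22 TPM with vesicles of TGF-β-stimulated neutrophils (SD, n = 3 each). The last group exceeded IL-1β alone by a log2 fold change of 0.39 (95% interval -0.22 to 1.00) and unstimulated vesicles by 0.41 (-0.20 to 1.02). Neither passed, with limma adjusted p = 0.86 and 0.36. With a pseudocount of 0.1 TPM the fold changes were 1.70 and 1.60, with adjusted p = 0.87 and 0.53. The exact two-sided permutation test gave p = 0.2 and 0.1, and 0.1 is the smallest that 3 against 3 libraries allow.

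**Figure D2:**
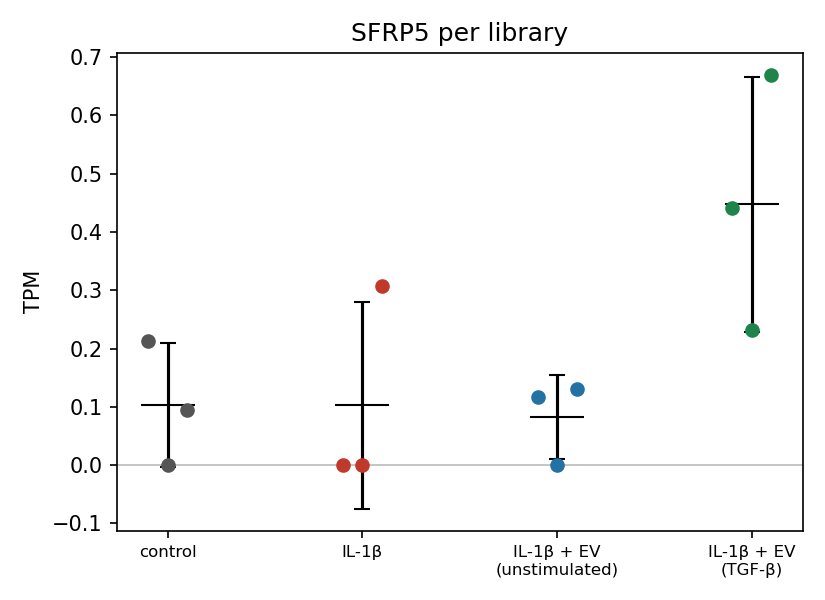
SFRP5 in TPM in each library (points) with group mean and SD (bars), on a linear axis. The libraries with vesicles of TGF-β-stimulated neutrophils average 0.45 TPM and the other groups 0.08 to 0.10 TPM.

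The second comparison asks what vesicles of unstimulated neutrophils changed in IL-1β-treated cells. No inflammatory gene changed past the threshold: CXCL1 was at 185 ± 23.4 TPM beside 161 ± 15.3 TPM, IL6 at 17.4 ± 1.23 beside 14.02 ± 0.38 TPM and MMP13 at 6.81 ± 1.72 beside 4.34 ± 1.32 TPM. Of 15 cytokine and chemokine genes 13 had a positive fold change, led by IL33 (0.90), CXCL3 (0.89), CXCL8 (0.72) and CXCL6 (0.55), with camera adjusted p = 0.19 for the list. Of 35 interferon-stimulated genes 26 had a positive fold change (median 0.24), with camera adjusted p = 0.19, or 0.85 with an estimated correlation. The limma test called 1 gene, ENSG00000278421, named here after its values were seen. It is a 71 bp row on chromosome X opposite FTX, at 6.49 ± 3.05 TPM with these vesicles and listed at 0 in all 9 other libraries. All 71 bp overlap exons of FTX, so its value is uncertain. The count was 0 with a pseudocount of 0.1, a filter at 5 TPM, which this gene does not reach, or the replicate number as a block. With only the groups compared 1 gene was called, but it was lower with vesicles, so ENSG00000278421 lost its call there too. At an unadjusted p under 0.05 there were 2291 genes, 12.55% where chance gives 5%. This number was 768 without library 1 of this vesicle group, 611 without library 3, 363 without both, 800 without IL-1β replicate 1 and 4853 without library 2.

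Genes with symbols that had the smallest unadjusted p were MIR3189 (3.43), SNORA14B (2.86) and MIR3197 (2.34), higher, and MIR5695 (-2.90), RPL21P89 (-1.52) and MIR3176 (-1.21), lower; none passed, with limma adjusted p of 0.11 to 0.40. All 6 are short RNA genes or a processed pseudogene, so their values are uncertain. Ribosomal protein genes (6 of 34 positive, median -0.11; RPL8 -0.32, RPL3 -0.30) and glycolysis and hypoxia genes (median -0.13; GAPDH -0.30) were called lower by camera, with no member past the threshold and adjusted p = 0.85 with an estimated correlation for both. The glycolysis and hypoxia list lost its call without IL-1β replicate 2 (median -0.058, adjusted p = 0.51) or library 2 of this vesicle group (-0.075, adjusted p = 0.49), and its median was -0.21 without IL-1β replicate 3. The ribosomal median was -0.049 without library 1, -0.18 without library 2 and -0.17 without IL-1β replicate 1. Libraries 1 and 3 of this group stood apart from the other libraries, at 51.9 and 65.1 on the first principal component, while library 2 lay at -0.20; without libraries 1 and 3 the ribosomal median was 0.03. Without library 2 the count rose from 1 to 665 genes, 656 of them higher, and it was 0 without IL-1β replicate 2 or 3 and 3 without IL-1β replicate 1 or library 3.

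The third comparison asks the same of vesicles from TGF-β-stimulated neutrophils. Interferon-stimulated genes were lower than with IL-1β alone in 32 of 35 cases, with a median log2 fold change of -0.28 beside -0.10 for all genes. XAF1 (-0.62), IFI44L (-0.59), IRF9 (-0.52) and OAS3 (-0.52) had the largest differences, and no member passed. CXCL1 was at 177 ± 30.6 TPM, IL6 at 14.7 ± 1.84 TPM, C3 at 47.6 ± 8.16 TPM and MMP13 at 4.91 ± 1.34 TPM. Of 22 NF-κB response genes 3 had a positive fold change (median -0.14), with camera adjusted p = 0.18 and fry adjusted p = 0.16. Of 24 immediate early genes 4 did (median -0.14, camera adjusted p = 0.18). Of 15 cytokine and chemokine genes 6 did (median -0.16, camera adjusted p = 0.97). The limma test called 0 of 18257 genes, with 989 at an unadjusted p under 0.05 (5.42%) and a smallest adjusted p of 0.35. The 989 became 1593 without IL-1β replicate 1, 544 without IL-1β replicate 2, and 440 and 570 without libraries 2 and 3 of this vesicle group. It called 3 genes without IL-1β replicate 1, 4 without replicate 2 and 1 without replicate 3 of this vesicle group.

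The mean level of the 35 interferon genes was 4.79 ± 0.11 log2 units with IL-1β alone, 4.52 ± 0.22 with these vesicles, 4.99 ± 0.04 with unstimulated vesicles and 3.50 ± 0.20 in control cells (SD, n = 3 each). Camera called the interferon list lower at adjusted p = 0.00017, with adjusted p = 0.64 with an estimated correlation. The call was lost without library 3 of this vesicle group, where the list median was -0.16 (adjusted p = 0.26), and without IL-1β replicate 3 (-0.23, adjusted p = 0.052). Mitochondrial transcripts (median 0.23; MT-CO3 0.47) and NRF2 and oxidative stress genes (median 0.07; PRDX1 0.26, NQO1 0.25, GCLC -0.33) were called higher, with adjusted p = 0.56 and 0.29 with an estimated correlation and 0.063 for both without IL-1β replicate 2. The mitochondrial median was 0.11 without IL-1β replicate 2 and 0.37 without IL-1β replicate 1, and the NRF2 median 0.034 and 0.14, and 0.11 without library 1 of this vesicle group. The symbols with the smallest unadjusted p were a repeated Y_RNA row (2.35), UPK3BL3P (1.23) and WDR83OS (1.06), higher, and EFCAB14-AS1 (-1.10), LAMA5-AS1 (-0.99) and INCA1 (-0.64), lower; none passed. EFCAB14-AS1, LAMA5-AS1, INCA1 and WDR83OS overlap exons of a gene on the other strand and are uncertain.

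**Figure D3:**
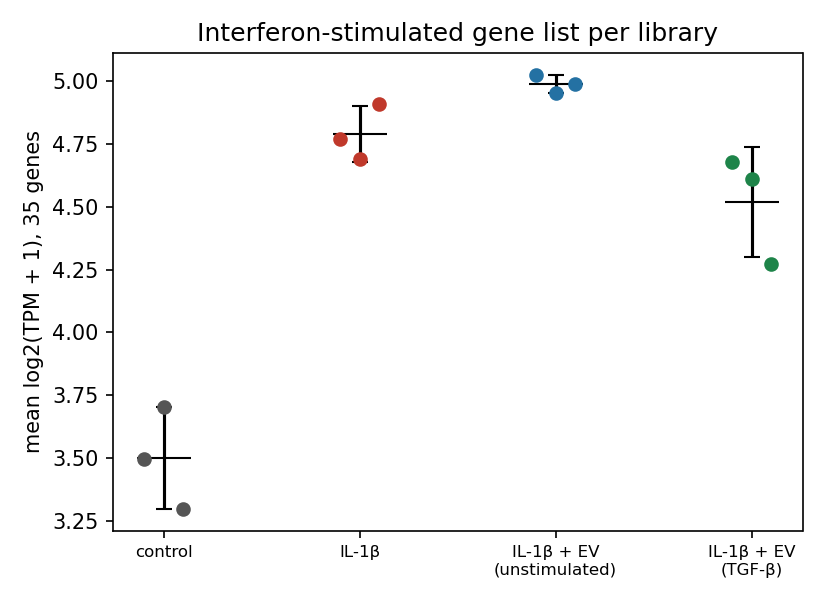
Mean log2(TPM + 1) of 35 interferon-stimulated genes in each library (points), with group mean and SD (bars). Group means are 3.50 in control cells, 4.79 with IL-1β, 4.99 with unstimulated and 4.52 with TGF-β-stimulated neutrophil vesicles.

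The fourth comparison is the direct test between the vesicle groups. Interferon-stimulated genes were lower with TGF-β-stimulated than with unstimulated neutrophil vesicles (median -0.53, 20 of 35 lower adjusted over the list alone; IFI44L -1.01, DDX60 -0.98, XAF1 -0.86, OAS2 -0.85), with 0 of 35 past the threshold over all genes and camera adjusted p = 0.00078, or 0.70 with an estimated correlation. With GC correction, chosen after the data were seen, the median was -0.18, and that of all genes went from -0.17 to 0.02. SOX9, the master regulator of cartilage, was at 26.4 ± 4.71 beside 51.9 ± 12.3 TPM, with limma adjusted p = 0.088 over all genes; it was at 57.1, 37.8 and 60.8 TPM in libraries 1, 2 and 3 with unstimulated vesicles and at 40.2 TPM in IL-1β replicate 2. None of the 11 tested genes of the cartilage list passed, and camera gave the list adjusted p = 0.85. Of 18 genes of glycosaminoglycan and hyaluronan synthesis and turnover, 9 were lower adjusted over the list alone, including the synthesis gene CSGALNACT2 (-1.07) and CEMIP (-0.90), which acts in hyaluronan breakdown, and 0 passed over all genes; camera gave this list adjusted p = 0.42, and 0.78 with an estimated correlation. CEMIP was at 7.63, 5.46 and 8.54 TPM in unstimulated-vesicle libraries 1, 2 and 3. The limma test called 1 gene, again ENSG00000278421 (-2.81), and 0 under the same 3 alternatives, with 5086 (27.9%) at an unadjusted p under 0.05 and 32.8% of genes separated where chance gives 10%. At thresholds chosen after the values were seen, 1 gene had an adjusted p under 0.06, 5 under 0.07 and 2359 under 0.1, 2211 of the last lower.

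Camera called interferon genes lower, and ribosomal proteins (median 0.10) and NRF2 genes (median 0.22, mean -0.02) higher, with adjusted p of 0.70, 0.70 and 0.61 with an estimated correlation; SLC7A11 (-0.93) and GCLM (-0.72) of the NRF2 list went the other way. The ribosomal median was 0.054 without unstimulated-vesicle library 1, 0.17 without library 2 and -0.033 without libraries 1 and 3, and 0.059 without library 2 of the TGF-β group. Without library 3 of the TGF-β group the interferon and NRF2 lists were not called (adjusted p = 0.059 and 0.054), with medians of -0.42 and 0.18, nor was the interferon list without unstimulated-vesicle library 2 (0.15), where its median was still -0.51. Fry, which does not compare a list with other genes, called 10 lists, each with a negative median. Among them were cytokines and chemokines (adjusted p = 0.027), NF-κB (0.027), interferon genes (0.038), Wnt ligands and receptors (0.027), Wnt targets (0.027) and Wnt inhibitors (0.040). All genes had a median of -0.17, and the NF-κB and Wnt inhibitor medians, both -0.15, were no lower. Fry called 0 lists in the comparisons of vesicle groups with IL-1β alone. Symbols with the smallest p were Y_RNA (2.35), HDAC11-AS1 (1.26) and MRPL27 (0.48), higher, and TAB3-AS2 (-3.22), CICP14 (-1.55) and EFCAB14-AS1 (-1.24), lower; none passed. The median of all genes was -0.17, and -0.002 after median-ratio scaling. The number at an unadjusted p under 0.05 was 2975 without unstimulated-vesicle library 1 and 2646 without library 3. Without unstimulated-vesicle library 2 the count was 4196, and without libraries 1 and 3 it was 2 with 516 at an unadjusted p under 0.05; among protein-coding genes alone it was 1266.

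**Figure D4:**
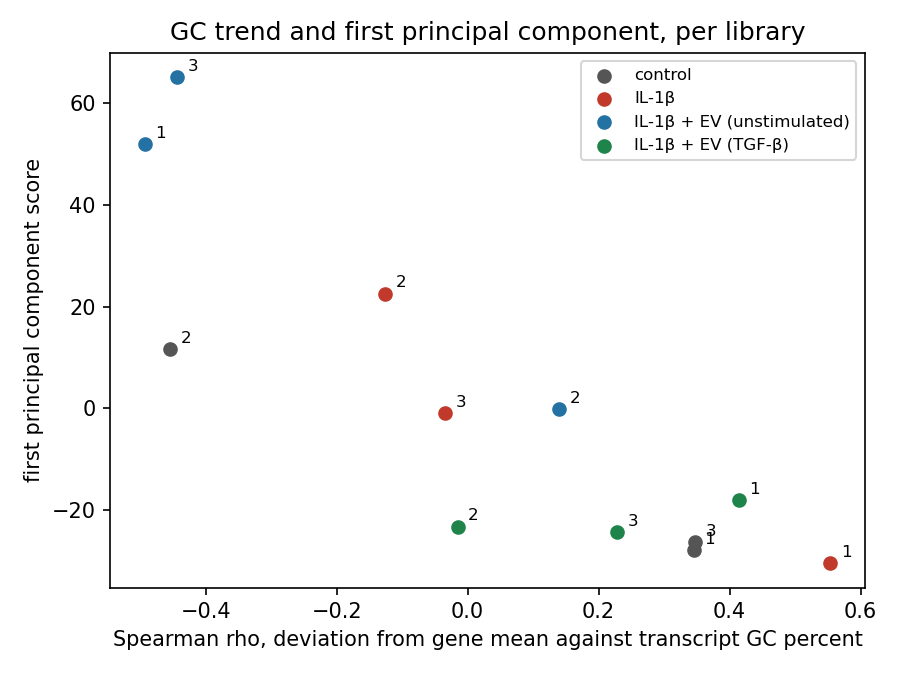
Score of each library on the first principal component (y) against the Spearman correlation, across genes, of its deviation from the gene mean with transcript GC percent (x); numbers are replicates. Unstimulated-vesicle libraries 1 and 3 lie at 51.9 and 65.1 with correlations of -0.49 and -0.44. Control replicate 2 lies at 11.6 with a correlation of -0.45.

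For the mean of both vesicle groups against IL-1β alone, the 35 interferon genes had a median of -0.04 and the 15 cytokine and chemokine genes a median of 0.16, and no gene passed. The limma test called 0 genes, with 518 at an unadjusted p under 0.05 and 1277 without unstimulated-vesicle library 2. Glycolysis and hypoxia genes (median -0.13; ADM -0.47, ALDOA -0.43) and ribosomal proteins (-0.05; RPLP2 -0.17) were called lower and mitochondrial transcripts (0.17; MT-CO3 0.30) higher by camera, each with adjusted p = 0.88 with an estimated correlation. Without IL-1β replicate 2 the glycolysis, ribosomal and mitochondrial lists lost their calls, with medians of -0.064, -0.026 and 0.054, and without IL-1β replicate 3 with medians of -0.14, -0.014 and 0.11 (adjusted p from 0.060 to 0.73). Without unstimulated-vesicle library 2 the glycolysis and mitochondrial lists missed the threshold (0.13 and 0.17) with medians still at -0.12 and 0.15. The ribosomal list missed it without libraries 1 or 3 of either vesicle group (0.11 to 0.44), with medians of -0.025 and -0.040 for unstimulated and -0.056 and -0.035 for TGF-β vesicles; its median was -0.12 without IL-1β replicate 1 and -0.093 without unstimulated-vesicle library 2. The mitochondrial median was 0.33 without IL-1β replicate 1. No gene was called with the same sign in both vesicle groups; simulated libraries without effects gave 0.01 on average, and the count could only be 0, since no gene was called with TGF-β vesicles.

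Genes changed by IL-1β kept the sign of their difference from control in 112 of 113 cases with unstimulated and 113 of 113 with TGF-β vesicles. Against control, 106 of the 113 genes were called in the same direction with unstimulated vesicles and 75 with TGF-β vesicles, where independent lists would share 1.23 and 0.515 raised genes and simulated libraries without effects shared 0. With no effects hardly any gene is called, so that 0 does not measure what the shared libraries add. In all, 203 and 85 genes were called against control. Of the 113, 43 were called with unstimulated vesicles without libraries 1 and 3, and 49 and 45 with TGF-β vesicles without libraries 1 and 2 of that group. The total for unstimulated vesicles was 102 and 114 without libraries 1 and 3 in turn, 48 without both and 2852 without library 2, and 117, 1053 and 111 without control replicates 1, 2 and 3; that for TGF-β vesicles was 55 and 49 without libraries 1 and 2 of that group. Both comparisons use the same 3 control libraries, which are too few to split, so part of the overlap may come from them. No gene changed by IL-1β was called in the opposite direction with either kind of vesicle; simulations gave 0 for both, and independent lists 0.0061 and 0. With 1 and 0 genes called against IL-1β alone, these counts could hardly differ from 0 and tell little about a reversal.

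S100A8 and S100A9, abundant in neutrophils, together with CSF3R, FCGR3B and CXCR2 summed to 2.21 TPM in library 3 with TGF-β vesicles and to 1.07 TPM or less in the other libraries. S100A9 averaged 0.74 ± 0.63 TPM with TGF-β vesicles beside 0.25 ± 0.22 TPM with IL-1β alone, and FCER1G 1.11 ± 0.83 beside 0.07 ± 0.12 TPM (SD, n = 3 each; both named after their values were seen). Other transcripts of the neutrophil list were higher also without vesicles: SRGN averaged 199, G0S2 24.1 and LCN2 8.82 TPM in control cells. Of 36 neutrophil transcripts listed, 10 were tested, with camera adjusted p = 0.83 with unstimulated and 0.24 with TGF-β vesicles against IL-1β alone. S100A8, S100A9, CSF3R, FCGR3B, CXCR2 and FCER1G were below the level set for testing. The list test therefore cannot decide whether vesicles carried in neutrophil RNA. The 6 tested platelet and red cell transcripts, of 16 listed, had camera adjusted p = 0.36 and 0.97, with the same limit.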

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

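The tests of GC content and of neutrophil RNA, both tests on the interferon genes, the shares of genes lying above or below unstimulated vesicles, and the comparisons of vesicle groups with control were chosen after the results were seen. ENSG00000278421 was noted because its level differed between the vesicle groups (-2.81 on the log2 scale, limma). Its call there and its call against IL-1β alone rest on the same unstimulated-vesicle libraries. All 71 bp of this row overlap exons of FTX on the other strand, so its value is uncertain. The interferon list (median -0.53), the NRF2 list (0.22) and the ribosomal protein list (0.10) differed between the vesicle groups by camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.70, 0.61 and 0.70). With GC correction the interferon median went from -0.53 to -0.18, and the median of all genes from -0.17 to 0.02. The list moved by more than all genes did, so a GC trend may hold a part of its difference between the vesicle groups.

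Unstimulated-vesicle libraries 1 and 3 stood apart from the other 10 libraries, including library 2 of their own group. A bias by GC content as the whole cause is argued against: removing each library's GC trend took the number of genes at an unadjusted p under 0.05 between the vesicle groups from 5000 to 4807, where chance gives 889. Removing the trend on gene length as well gave 4459. The share of the first component fell from 35.4% to 26.1% with the GC correction, with libraries 1 and 3 still at 38.4 and 51.3 and the next highest library at 20.1, so GC content may account for a part. Neutrophil messenger RNA carried in by the vesicles is argued against by its 5 abundant transcripts, which summed to at most 0.528 TPM in these libraries. Libraries 1 and 3 had the most rows at 1 TPM or more, at 18892 and 19456. The next highest library, IL-1β replicate 2, had 18467. Their deviations from the gene mean also had the highest correlations with gene length, 0.295 and 0.237, with control replicate 2 next at 0.147. Whether these traits come from library preparation or from the cells cannot be told, since read depth is unknown. Other differences in library preparation and a vesicle response that varied between cultures stay open.

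Interferon-stimulated genes were lower with TGF-β vesicles than with IL-1β alone. A GC trend is argued against, since the list median relative to all genes was -0.181 before and -0.184 after its removal. Chance with genes that vary together cannot be told apart from a vesicle effect: camera with an estimated correlation gave adjusted p = 0.638, and the exact permutation p of the library means was 0.1, the smallest that 3 against 3 libraries can give. The highest mean with TGF-β vesicles (4.677) lay close under the lowest with IL-1β alone (4.689). TGF-β vesicle library 3 (4.271) carried much of the difference, which was -0.271 with it and -0.146 without it, and without it the list was not called at the preset correlation (adjusted p = 0.26). Over the 18 alternatives the adjusted p ran from 3.8e-09 to 0.64. An effect of the TGF-β vesicles stays open as a hypothesis. Unstimulated vesicles lay on the other side of IL-1β alone, with a lowest library mean of 4.954 beside its highest of 4.911. The exact permutation test gave p = 0.1 there too. The difference between the vesicle groups therefore holds both shifts.

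SFRP5 was highest with TGF-β vesicles, at a mean below 1 TPM. Scatter at very low expression may account for the size of the difference: of 4552 genes with a mean of 0.1 to 0.3 TPM, 13.4% differed by at least as much between these vesicles and IL-1β alone, and 16.8% against unstimulated vesicles. Lying above all unstimulated-vesicle libraries in each library, as SFRP5 did, was less common, at 1.3% of these genes beside 6.83% that lay below. These unequal shares point to a shift between the groups, so 1.3% is not the share that scatter alone would give. No such share was computed against IL-1β alone, where the exact permutation test gave p = 0.2. Scatter and an effect of the vesicles on SFRP5 both stay open.

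Other splits of the same libraries were counted. For IL-1β against control, the 6-library fit called 54 genes and the highest of the 9 other splits 3; against control, unstimulated vesicles gave 68 and the highest other split 1, and TGF-β vesicles 39 and 3. For unstimulated vesicles against IL-1β alone the real split gave 1 gene and the highest other 2, for TGF-β vesicles 0 and 2, and between the vesicle groups 2 and 2. As many genes as the real split came from 1, 3, 10, 2, 1 and 1 of the 10 splits of IL-1β, unstimulated vesicles, TGF-β vesicles, the vesicle groups against each other, and each vesicle group against control, and 10 splits are too few for a share under 0.05. A real count of 0, as for TGF-β vesicles, is reached by every split and tells nothing of chance. This also holds for both vesicle groups against IL-1β alone, where all 84 splits gave as many as the real count of 0 and the highest gave 5368, with unstimulated-vesicle libraries 1 and 3 and IL-1β library 2 on one side, which points to a structure of the samples. For any difference among the groups, 100 splits were counted, the real one among them and the others drawn at random. Of these, 4, with the real one included, gave as many as the 123 genes, a share under 0.05. The highest gave 3151.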

How the results depend on the processing

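The GC correction, the removal of unstimulated-vesicle libraries 1 and 3, and protein-coding genes only were chosen after the data were seen. Of 191 results for the named IL-1β genes under the alternatives, 188 kept direction and call; CXCL8 lost its call in the fit of only the groups compared, and UPK3BL3P without control replicate 1 or 3. Among 297 results for genes named in vesicle comparisons, none reversed and 17 came to pass. Of 197 results for lists called with IL-1β, 154 kept their call and 43 lost it. Of 205 in vesicle comparisons, 154 kept it, 49 lost it and 2 reversed in the direction that camera gave. The ribosomal median between the vesicle groups also turned negative (-0.033) without unstimulated-vesicle libraries 1 and 3, where camera's direction stayed the same. Unless the construction of an alternative shows it, the cause was not tested. Depth is unknown, and TPM values give no measure of its effect.

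IL-1β against control gave 54 genes with only the groups compared, which has fewer libraries, and 78 to 120 when each library was left out. With a pseudocount of 0.1, a filter at 5 TPM or the replicate block, unstimulated vesicles against IL-1β and the vesicle groups against each other gave 0 genes each. With no filter they gave 5 and 4 genes, TGF-β vesicles against IL-1β 1, both vesicle groups 2, the opposite calls 1 for either kind of vesicle and the shared calls 1. The vesicle groups against each other gave 2 genes with only those groups, 3 with no trend and 1266 among protein-coding genes, where unstimulated vesicles against IL-1β gave 0. With only the groups compared, 1 opposite call appeared for unstimulated vesicles. Without libraries 1 and 3 the counts were 4 for unstimulated vesicles, 2 between the vesicle groups, 1 for both, 1 opposite call and 70 for any group. The lone remaining library is then assumed to vary like the other groups.

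With an estimated correlation 3 lists were called for IL-1β and 0 in every vesicle comparison; fry, which does not compare a list with other genes, called 7 for IL-1β, 10 between the vesicle groups and 0 in the others. Lists for TGF-β vesicles against IL-1β were 6 with no filter and 5 with median-ratio scaling, GC correction or protein-coding genes; between the vesicle groups they were 5 with no filter or GC correction and 1 with quantile normalization. Lists for unstimulated vesicles were 1 at 5 TPM or with quantile normalization, and 5 with only the groups compared or without libraries 1 and 3. Lists for both vesicle groups were 1 with quantile normalization, GC correction or without mitochondrial and ribosomal RNA, and 6 without libraries 1 and 3, where IL-1β lists were 7 and the ribosomal median turned from negative to 0.034 for unstimulated vesicles and 0.012 for both.

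Leaving out each library in turn gave 0 to 665 genes for unstimulated vesicles, 0 to 4 for TGF-β vesicles, 0 to 4196 between the vesicle groups, 0 to 2 for both and 69 to 1500 for any group. The values 665, 4196 and 1500 came without unstimulated-vesicle library 2. Lists ranged from 5 to 12 for IL-1β, 1 to 6 for unstimulated vesicles, 2 to 5 for TGF-β vesicles, 1 to 5 between the vesicle groups and 0 to 4 for both. Opposite calls ranged from 0 to 2 for unstimulated and 0 to 3 for TGF-β vesicles, and shared calls from 0 to 2. The log2 fold change of SFRP5 ranged from -0.14 to 0.063 with IL-1β and from -0.081 to 0.11 with unstimulated vesicles, where it was 0.10 with a pseudocount of 0.1 and 0.092 with GC correction. With TGF-β vesicles it lay between 0.29 and 0.52 when each library was left out, at 1.70 with a pseudocount of 0.1 and at 0.54 with quantile normalization, and it did not pass under any alternative.

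The replicate numbers do not appear to pair the libraries: correlations of deviations between libraries of the same number ran from -0.33 to 0.20, with a median of -0.009, and 0 of 12 libraries matched best with their own number. With the replicate block, IL-1β against control gave 87 genes.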

Other observations

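The counts of raised genes and their simulation were chosen after the data were seen. Of the 112 genes raised by IL-1β, 89 (79.5%) were lower with TGF-β vesicles than with IL-1β alone and 42 (37.5%) were lower with unstimulated vesicles. Genes chosen for being high with IL-1β fall back by chance: in 100 simulations with IL-1β effects and no vesicle effect, 65.0% (58.6% to 70.8%) and 64.4% (57.4% to 70.8%) were lower. The simulation treats genes as independent, so its ranges are too narrow. It also holds no shift of all genes, whose medians were -0.099 with TGF-β and 0.071 with unstimulated vesicles beside -0.197 and 0.065 for the raised genes; with unstimulated vesicles the raised genes thus lay near all genes, and the shifts move both counts away from the simulated ones. Between the vesicle groups 87 of the 112 were lower with TGF-β vesicles, with a median of -0.23 beside -0.17 for all genes.

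Interferon genes themselves were barely measured; the genes named here were chosen after their values were seen. IFNB1 was listed at 0 in 11 of the 12 libraries, and IFNL1 averaged 0.351 TPM in control and 0.764 TPM in IL-1β cells, with SDs of 0.394 and 1.07. IRF7, which drives interferon transcription, went from 19.6 ± 4.15 to 49.0 ± 5.75 TPM (SD, n = 3 each).

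Fold changes of the vesicle groups against IL-1β alone had a correlation across genes of 0.171 and a covariance of 0.0188, below the 0.501 and 0.0468 that the shared IL-1β libraries give in simulations without effects. Genes are not independent replicates.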
